A study of Homo sapiens with 19 samples.

How the data were processed

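RNA-seq of poly(A) RNA was analysed for 17 libraries of MDA-MB-231 cells in 6 groups. Cells were kept in L15 medium with 10% fetal bovine serum and transfected with 30 nM siRNA, and RNA was taken with TRIzol, per the labels' protocols. A further 2 samples, H3K27ac CUT&Tag profiles of control and HMGN5-depleted cells, are not analysed here. Groups were taken from the sample titles and replicates from the numbers in them.

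Each deposited table lists the same 175775 Ensembl transcripts with a length, an effective length, a TPM value and an estimated count of reads, per the file headers. The submitters' processing notes name Salmon 1.4.0, CASAVA, Bowtie2 and HOMER and the builds GRCh38 and hg38. Which release of the transcript set was used, and with which mapping and bias options, is not given in the sources used here. The estimated counts in the deposited files are expected counts that need not be whole: a read that several transcripts could explain is divided between them by a model, so transcripts of 1 gene, paralogs and pseudogenes can trade reads, and overlapping and antisense genes are not separated where strand was not used. The deposited TPM values are scaled by effective length to the same total in each library. Transcripts under 300 bases took 1.15% to 1.7% of the estimated reads but 38.8% to 45.4% of the TPM, because their effective lengths are short, so TPM was used only to describe levels and all tests used the counts. Length and effective length are in bases.

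Tests had been planned per gene, with reads summed over transcripts. The files do not pair transcripts with genes, and the tables at hand pair only gene IDs with symbols, so each test was run per transcript. The gene lists chosen before the data were examined, the check of STAT3 and HMGN5 levels and the sums per gene were not run for the same reason. Transcripts whose estimated reads were within 0.0015 of a whole number in all 17 libraries were treated as having unshared reads (462 tested in the siRNA experiment, 437 in the lentiviral one, with 0.741% to 0.959% of the reads of a library). That class was defined after the files were opened, and counts of calls within it come from separate fits with adjustment over the class alone. Named transcripts were the 2 with the largest rise and the 2 with the largest fall in each of 4 comparisons, among those with an adjusted p under 0.05, a mean of at least 2 CPM, no overlap between the libraries of the compared groups, and unshared reads. The rule fixed before the data were examined took 6 rising and 6 falling genes with a symbol under the same limits without the last condition, together with STAT3, HMGN5 and members of the gene lists. It was narrowed after the files were opened, because IDs without names left no other guard against shared reads and no way to find listed genes.

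Estimated counts were rounded to whole numbers. The 8 libraries of the siRNA experiment and the 9 of the lentiviral experiment were fitted apart with edgeR 4.0.16 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest on group means, R 4.3.3), with Benjamini-Hochberg adjustment over the transcripts tested and a threshold of 0.05. Fold changes used the default prior count of edgeR. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the test statistic. The difference of the STAT3 siRNA effect between experiments was an interaction contrast in 1 fit of all 17 libraries. CPM values were scaled by TMM within each experiment. Lists of transcripts were tested with camera of limma 3.58.1 (preset correlation 0.01, repeated with an estimated correlation), with adjustment over 12 tests of 4 lists in 3 comparisons. For comparisons that share libraries, correlations and covariances are printed beside 20 simulations of unchanged groups and beside the overlap that independent lists would have. For the STAT3 siRNA and HMGN5 comparisons, the covariance was also taken on the same transcripts without each library and with different siSTAT3_Vec libraries in the 2 comparisons, each beside 5 simulations.

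The depth and the spread of the libraries and the number of changed transcripts together set which changes could be called, and none of these was varied in the simulations. In simulated data with 200 transcripts of at least 10 CPM changed either 2-fold or 4-fold, with the means, spread and library sizes of these samples, 25% of 4-fold changes were recovered for siSTAT3 vs NC (67536 transcripts) and 35% for siHMGN5 vs NC (67543). For siSTAT3_Vec vs NC_Vec 84% were recovered (63539 transcripts), and for siSTAT3_HMGN5 vs siSTAT3_Vec 82% (63592). Recovery of 2-fold changes was 1%, 0%, 32% and 31% in the same order, and the false calls numbered 0, 0, 1 and 5. The spread used for the siRNA experiment includes the difference between the NC pairs. The 200 changed transcripts are fewer than those called in each of these comparisons, which makes the adjusted threshold stricter. These shares therefore do not measure the recovery in the real data.

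Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile scaling and no scaling factor, no low-count filter and a filter of 2 CPM, an effective-length offset, limma-voom, the DESeq2 Wald test (version 1.42.0), stricter thresholds, fits with only the compared groups, a replicate block, each NC pair alone, and leaving out each library. The fits limited to unshared reads, and those with 1 NC pair for the difference between experiments, the correlations and the lists, were added after the data were seen.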

Results

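The transcriptome of MDA-MB-231, an established human cell line of triple-negative breast cancer, was measured by sequencing poly(A) RNA after depletion of STAT3 or HMGN5. STAT3 is a transcription factor downstream of the JAK kinases, and HMGN5 is a nucleosome-binding protein of the high mobility group N family. In the siRNA experiment, cells received a control siRNA (NC, 4 libraries), an siRNA against HMGN5 (siHMGN5, 2 libraries) or an siRNA against STAT3 (siSTAT3, 2 libraries), each at 30 nM. In the lentiviral experiment, cells received control siRNA with an empty vector (NC_Vec, 3 libraries), STAT3 siRNA with the empty vector (siSTAT3_Vec, 3 libraries) or STAT3 siRNA with lentiviral HMGN5 (siSTAT3_HMGN5, 3 libraries). Each library of the siRNA experiment held 19114033 to 19509422 estimated reads, and each of the lentiviral experiment held 22500086 to 23047081. Reads were assigned to 175775 transcripts, of which 81764 to 86187 had at least 1 read in a library. A count of 3 reads corresponded to 0.154 to 0.157 CPM (counts scaled by library size) in the siRNA experiment and to 0.13 to 0.133 CPM in the lentiviral experiment. The files list Ensembl transcript IDs and do not pair them with gene names. Changes are therefore given per transcript, at most 2 raised and 2 lowered IDs are named per comparison, and the knockdown of STAT3 and HMGN5 was not checked at their own transcripts.

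Libraries of each treated group lay close together, but the NC group held 2 pairs that stood apart. NC replicates 1 and 2 differed from NC replicates 3 and 4 with a mean chi-square of 41.6 to 47.9 per transcript with unshared reads (361 to 411 transcripts with at least 20 reads), against 1.92 and 2.3 inside the pairs and 1.74 to 5.83 between replicates of the other groups. In a fit with the pairs as separate groups, 3262 of 74346 transcripts differed between NC replicates 3 and 4 and NC replicates 1 and 2, 1444 higher and 1818 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Calls of this number, with a median absolute log2 fold change of 1.05, thus arose between libraries of the same treatment. In that fit, siSTAT3 had 5298 and siHMGN5 4163 calls against NC replicates 1 and 2, and 7321 and 7656 against NC replicates 3 and 4. Each siRNA group is 1 pair of libraries, so a difference between pairs cannot be told apart from the treatment. Counts of transcripts and the named transcripts are given below with all 4 NC libraries and against each pair. The siHMGN5 and siSTAT3 libraries also stood apart from NC in the share of reads on transcripts under 300 bases, at 1.56% to 1.7% and 1.57% to 1.59% against 1.15% to 1.26% in NC. No pair of libraries agreed within counting noise, so each was counted as 1 sample. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

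**Figure D1:**
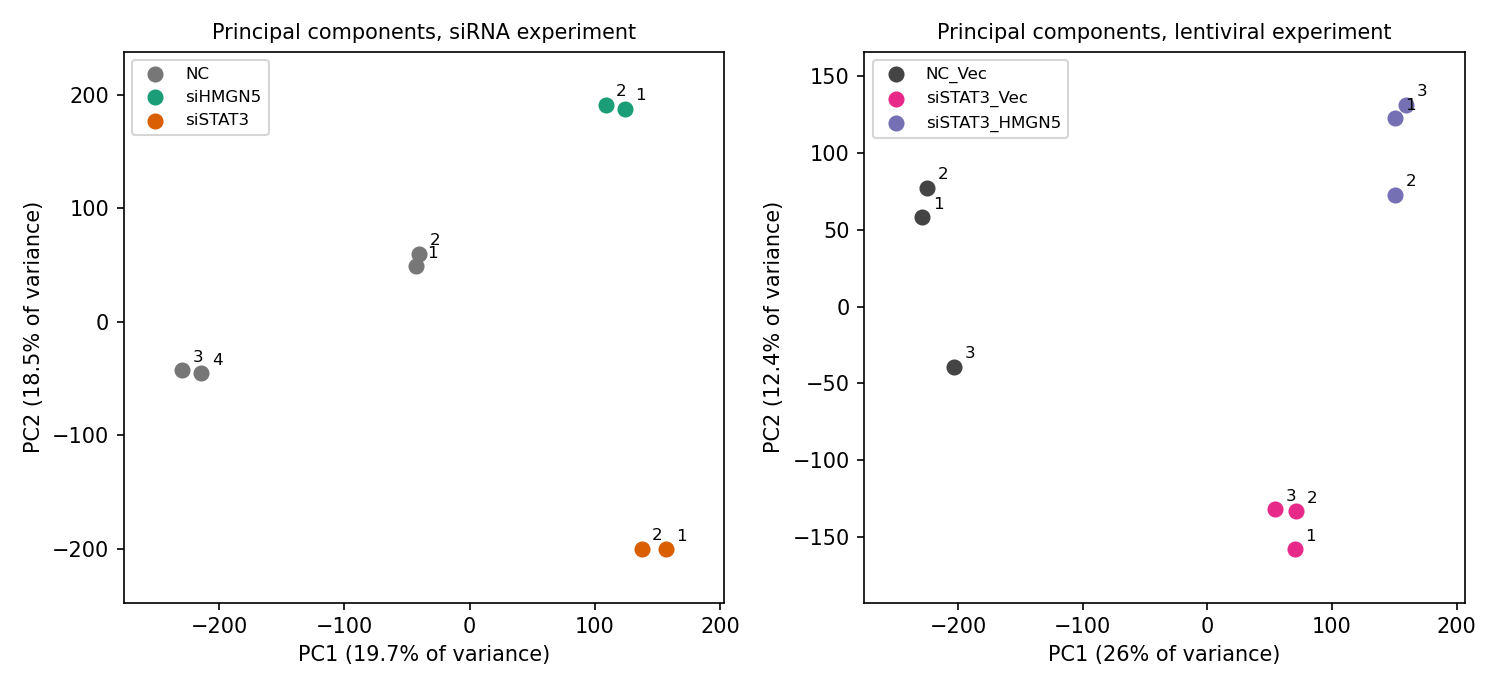
Principal components of log2 CPM over the transcripts tested, for the 8 libraries of the siRNA experiment (left) and the 9 of the lentiviral experiment (right); points are libraries, numbers are replicates, and axes give the component scores with their share of the variance. NC replicates 1 and 2 lie at -42.6 and -40.2 on PC1, and NC replicates 3 and 4 at -230 and -214.

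The effect of STAT3 depletion was addressed first by siSTAT3 against NC. Compared with NC, ENST00000319234.4 was 6.04-fold lower, at 47.4 ± 17.5 CPM in NC (SD, n = 4) and 7.84 ± 0.722 CPM in siSTAT3 (SD, n = 2), with a log2 fold change of -2.60 ± 0.39 (SE, adjusted p = 0.0178). ENST00000375256.4 was 5.36-fold lower, from 43.2 ± 16.8 CPM to 8.05 ± 1.02 CPM (log2 fold change -2.42 ± 0.40, adjusted p = 0.0237). ENST00000369512.2 was 9.9-fold higher, from 1.99 ± 0.935 CPM to 19.8 ± 1.1 CPM (log2 fold change 3.31 ± 0.47, adjusted p = 0.0154). ENST00000268042.6 was 7.63-fold higher, from 3.34 ± 1.66 CPM to 25.5 ± 2.16 CPM (log2 fold change 2.93 ± 0.43, adjusted p = 0.0174). Against NC replicates 1 and 2 only, the log2 fold changes of the 4 transcripts were -3.00, -1.86, 2.87 and 2.42 in that order, and against NC replicates 3 and 4 only they were -2.05, -2.84, 3.92 and 3.71 (adjusted p of at most 0.0203).

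Of 74346 transcripts tested, 1011 were higher and 2170 lower in siSTAT3 than in NC, of which 568 and 1515 changed at least 2-fold. Among the 15934 transcripts with a mean of at least 10 CPM, 676 were higher and 1567 lower. The limma-voom test gave a more even split, 1664 higher and 1877 lower. Among 462 transcripts treated as having unshared reads the balance was the other way, with 102 higher and 65 lower. These had a fit of their own with adjustment over the 462 alone (36.1% called, against 4.28% of all). The balances therefore stand at unlike thresholds. Against NC replicates 1 and 2 alone, 2069 transcripts were higher and 3229 lower, and against NC replicates 3 and 4 alone, 3178 were higher and 4143 lower. Against both pairs, 3385 transcripts changed the same way (1039 higher, 2346 lower), including 2778 of the 3181 called with all NC libraries, and 133 changed in opposite ways. Without siSTAT3 replicate 1 or 2, 805 or 775 transcripts passed the test and none of the 4 named transcripts did (adjusted p 0.0818 to 0.172, same direction), with the lone library assumed to vary like the other groups. The call of ENST00000375256.4 also ended without NC replicate 4 (adjusted p = 0.0551).

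**Figure D2:**
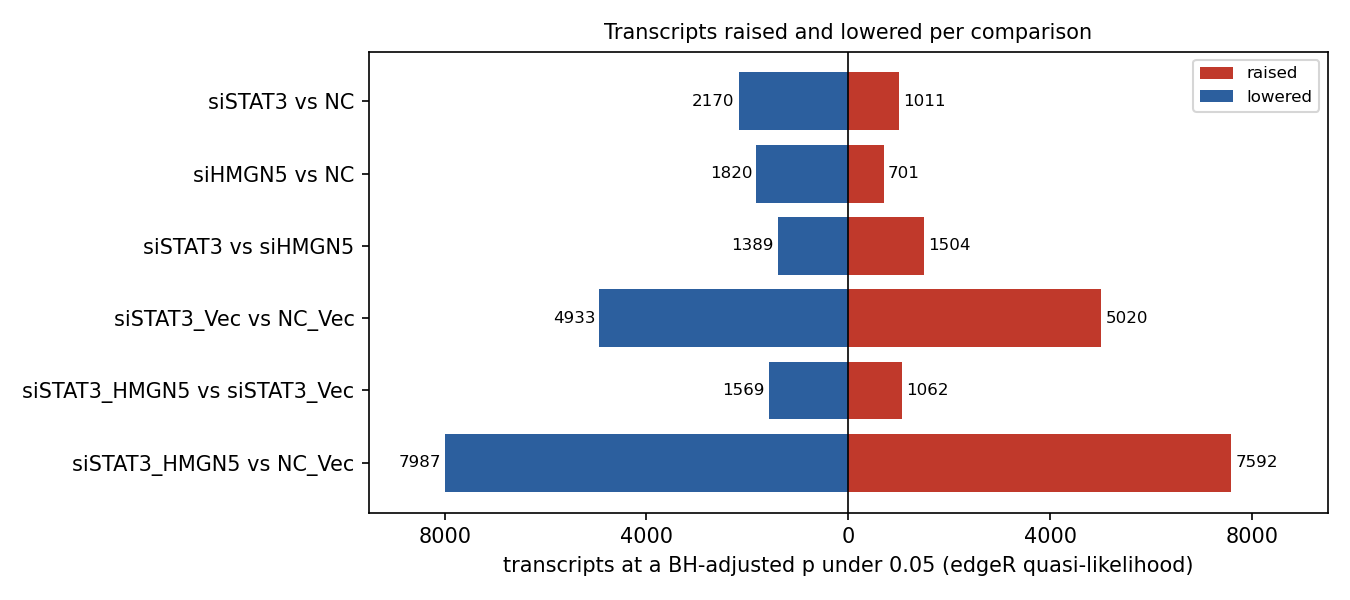
Transcripts past a Benjamini-Hochberg adjusted p of 0.05 in each of the 6 comparisons (edgeR quasi-likelihood test); bars to the right count transcripts higher in the first-named group and bars to the left those lower. The counts run from 2521 in siHMGN5 vs NC to 15579 in siSTAT3_HMGN5 vs NC_Vec.

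HMGN5 depletion was addressed by siHMGN5 against NC. ENST00000295927.3 was 8.84-fold lower, from 20.7 ± 7.45 CPM in NC (SD, n = 4) to 2.34 ± 0.251 CPM in siHMGN5 (SD, n = 2), with a log2 fold change of -3.15 ± 0.40 (SE, adjusted p = 0.0124). ENST00000275300.2 was 5.08-fold lower, from 4.93 ± 0.739 CPM to 0.966 ± 0.0568 CPM (log2 fold change -2.35 ± 0.30, adjusted p = 0.0128). ENST00000318978.5 was 8.38-fold higher, from 11.7 ± 7.8 CPM to 98.4 ± 11.7 CPM (log2 fold change 3.07 ± 0.60, adjusted p = 0.0476). ENST00000268042.6, also raised in siSTAT3, was 5.06-fold higher at 16.9 ± 0.0228 CPM (log2 fold change 2.34 ± 0.43, adjusted p = 0.0408). Against NC replicates 1 and 2 only, the log2 fold changes of the 4 were -2.62, -2.16, 2.42 and 1.83 in that order, and against NC replicates 3 and 4 only they were -3.53, -2.51, 4.28 and 3.14 (adjusted p of at most 0.0358).

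In all, 701 transcripts were higher and 1820 lower in siHMGN5 than in NC, of which 391 and 1189 changed at least 2-fold. At a mean of at least 10 CPM, 469 of 15934 transcripts were higher and 1390 lower. With limma-voom, 1305 were higher and 1660 lower, and among the 462 transcripts with unshared reads, 59 were higher and 49 lower. Against NC replicates 1 and 2 alone, 1398 transcripts were higher and 2765 lower, and against NC replicates 3 and 4 alone, 3277 were higher and 4379 lower. Against both pairs, 2804 changed the same way (741 higher, 2063 lower), including 2201 of the 2521 called with all NC libraries, and 116 changed in opposite ways. The calls of ENST00000318978.5 and ENST00000268042.6 lay close to the threshold: without any 1 NC library or either siHMGN5 library their adjusted p lay between 0.0537 and 0.21. With every library in place, both calls also ended without a low-count filter (adjusted p = 0.0648 and 0.0567) and with only the compared groups in the fit (adjusted p = 0.0904 and 0.0848). That of ENST00000318978.5 ended with the effective length offset too (adjusted p = 0.0528). The call of ENST00000275300.2 ended with a replicate block in the fit (log2 fold change -2.16, adjusted p = 0.0793). There NC replicates 3 and 4 are each alone in a block and drop out. Without NC replicate 3 or 4, 1570 or 1537 transcripts passed the test. Without siHMGN5 replicate 1 or 2, 630 or 551 passed, the calls of all 4 named transcripts ended, and their direction held.

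**Figure D3:**
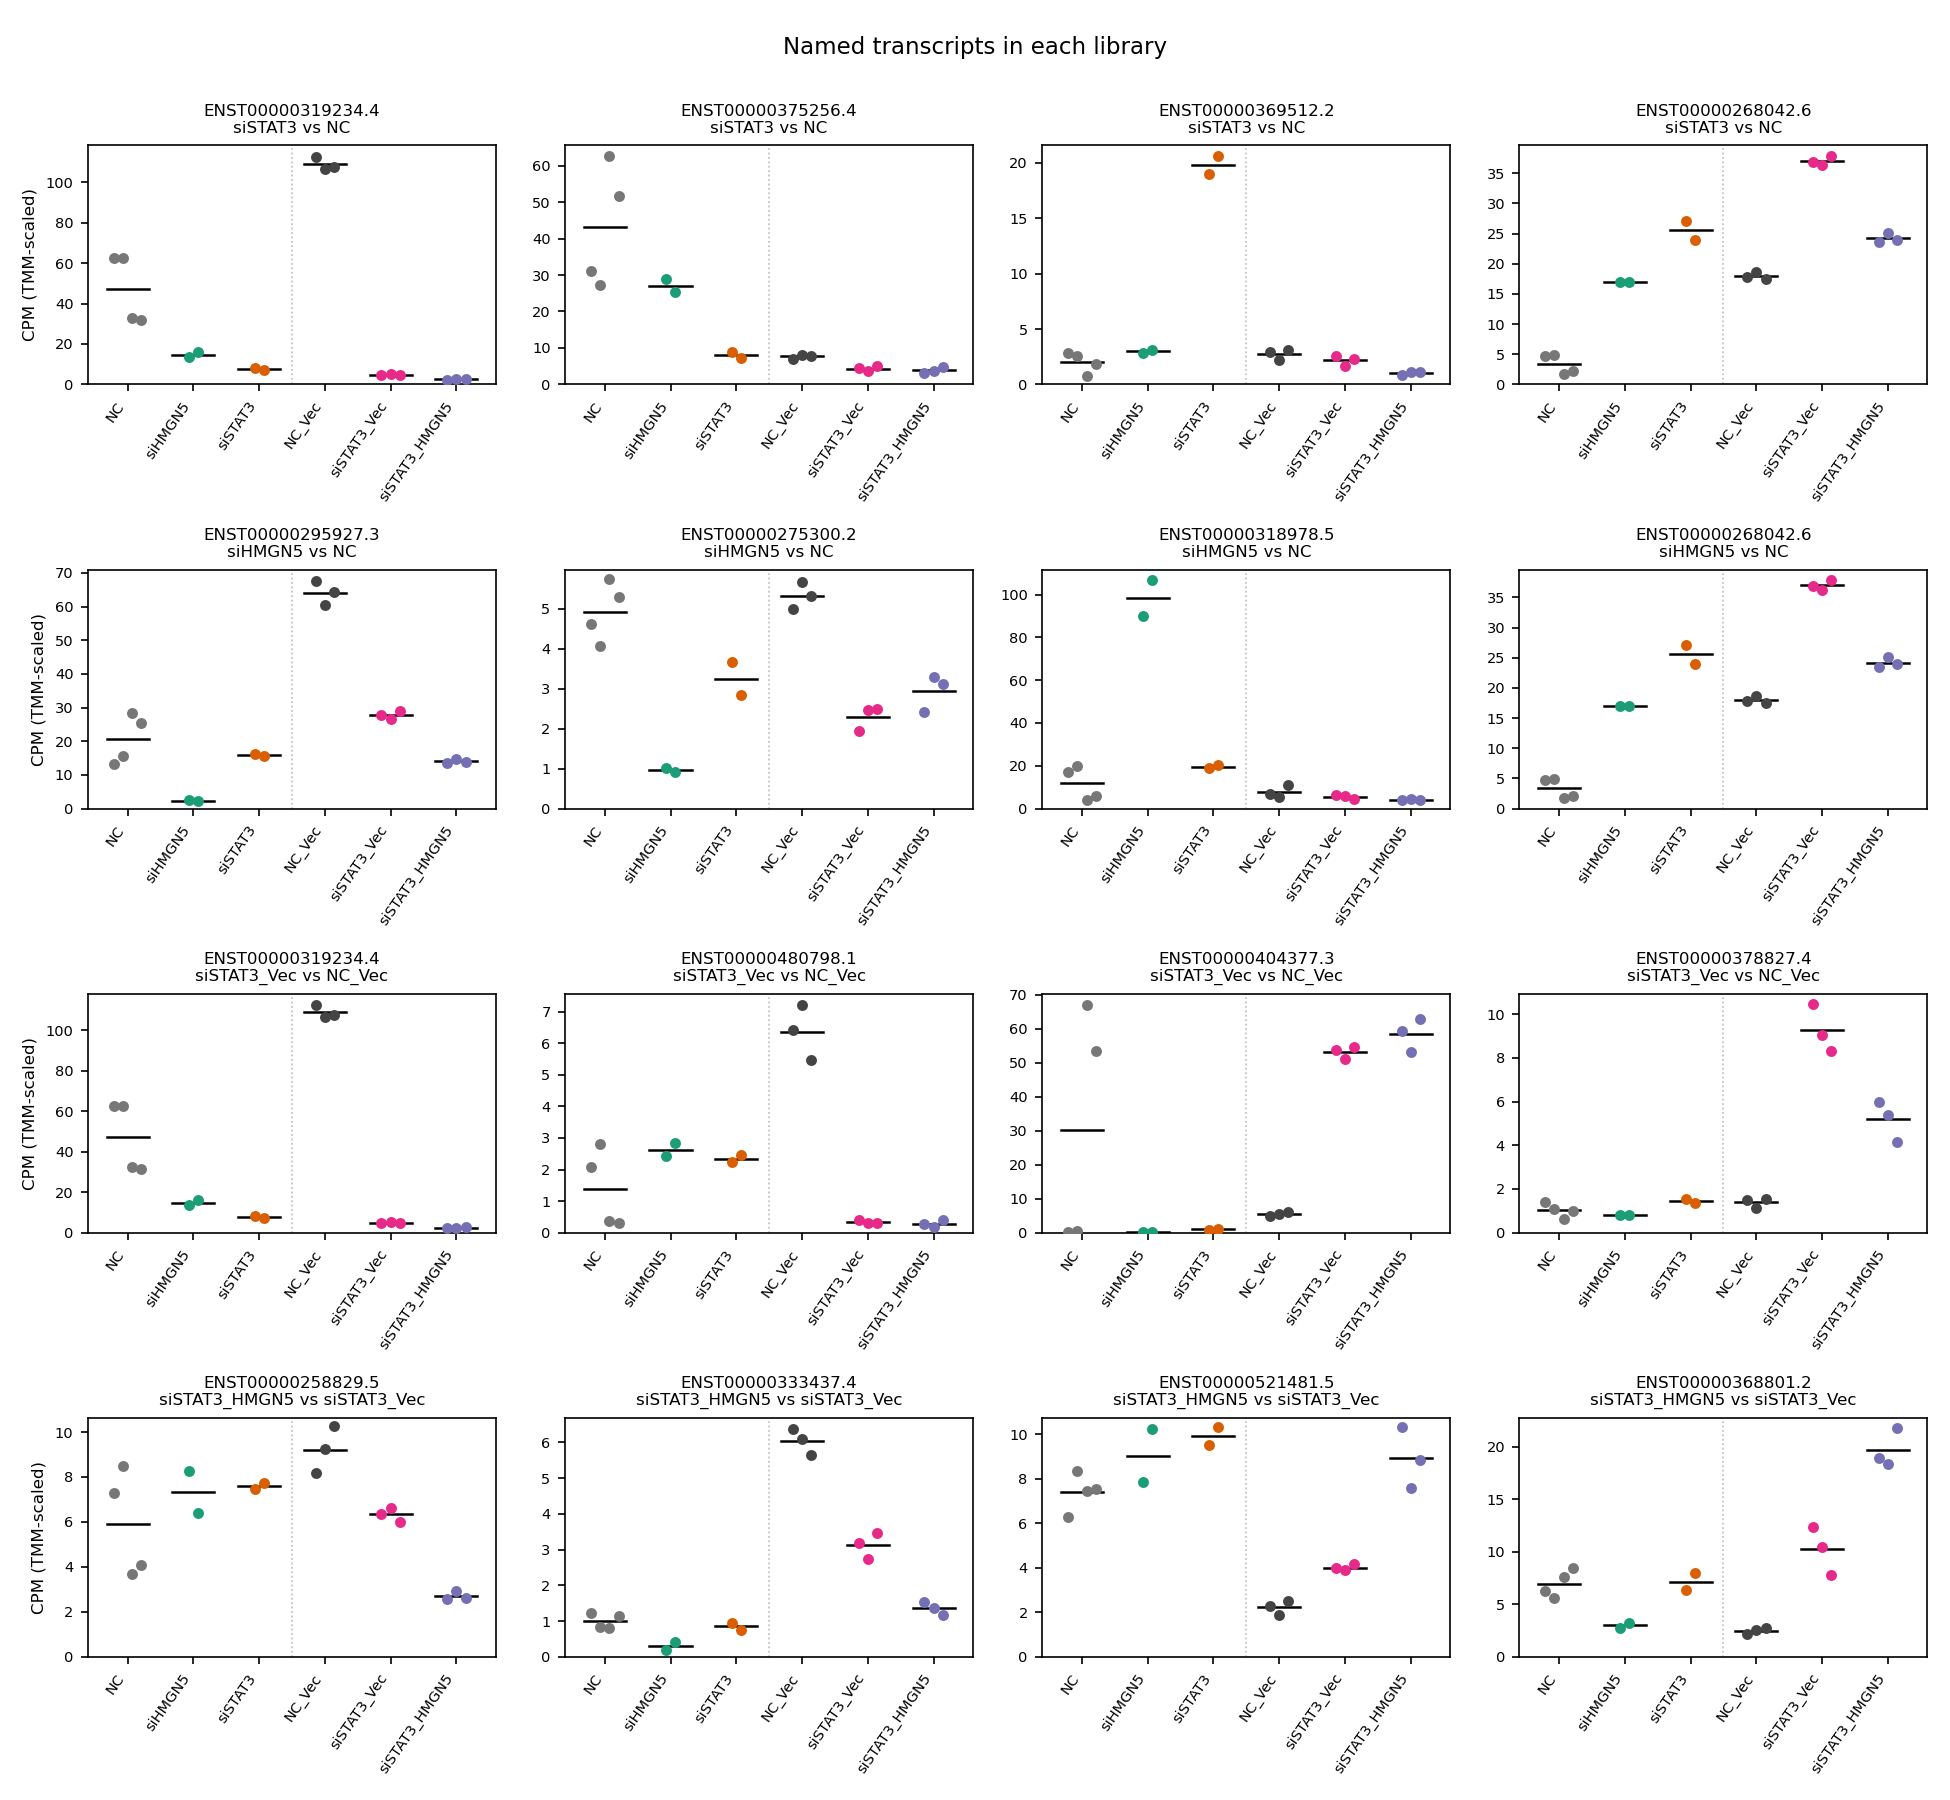
CPM (TMM-scaled within each experiment) of the named transcripts in all 17 libraries; points are libraries, horizontal lines group means, each panel starts at 0 and its title gives the transcript and the comparison that named it, and the dotted line parts the experiments. ENST00000319234.4 runs from 31.7 to 62.6 CPM in NC and from 7.33 to 8.35 CPM in siSTAT3.

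Whether the 2 knockdowns moved the same transcripts was asked of the fold changes against NC. Both passed the test for 833 transcripts, and 753 of them moved the same way, 234 higher and 519 lower in both. Independent lists of these sizes would share 62.6 transcripts moving the same way and 45.2 moving opposite ways. The comparisons share the NC libraries, however. Across 74346 transcripts the fold changes correlated at r = 0.312 (Pearson; rho = 0.303), and 20 simulations of unchanged groups against the same controls gave a mean r of 0.359. The covariance was 1.41, against a simulated mean of 1.04 (1.01 to 1.09). The simulations drew the 4 NC libraries alike, without the difference between the NC pairs, so this excess cannot be read as a shared effect. With separate NC pairs for the 2 knockdowns, r was 0.027 and 0.0591 and the covariance was 0.0752 and 0.158. Of the transcripts called in both, 431 of 628 and 230 of 296 moved the same way. These correlations are across transcripts, which are not independent replicates.

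A direct comparison of the knockdowns found 1504 transcripts higher and 1389 lower in siSTAT3 than in siHMGN5. Among the named transcripts, 2 differed between them. ENST00000295927.3 was 6.73-fold higher in siSTAT3 (log2 fold change 2.75 ± 0.41, adjusted p = 0.0191) and ENST00000275300.2 was 3.35-fold higher (log2 fold change 1.74 ± 0.32, adjusted p = 0.0341). Without siSTAT3 replicate 1 or 2, 844 or 935 transcripts passed the test, and without siHMGN5 replicate 1 or 2, 926 or 972 did.

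In the lentiviral experiment, STAT3 siRNA was compared with control siRNA in cells carrying the empty vector. ENST00000319234.4 was again lower, from 109 ± 3.28 CPM in NC_Vec (SD, n = 3) to 4.89 ± 0.267 CPM in siSTAT3_Vec (SD, n = 3), a 22.3-fold difference with a log2 fold change of -4.48 ± 0.08 (SE, adjusted p = 1.9e-06). ENST00000480798.1 was 18.6-fold lower, from 6.37 ± 0.884 CPM to 0.338 ± 0.0513 CPM (log2 fold change -4.21 ± 0.35, adjusted p = 0.000236). ENST00000404377.3 was 9.61-fold higher, from 5.53 ± 0.634 CPM to 53.2 ± 1.91 CPM (log2 fold change 3.26 ± 0.10, adjusted p = 6.97e-06). ENST00000378827.4 was 6.59-fold higher, from 1.4 ± 0.229 CPM to 9.27 ± 1.09 CPM (log2 fold change 2.72 ± 0.21, adjusted p = 0.000191). In the siRNA experiment ENST00000404377.3 lay at 0.203 and 0.574 CPM in NC replicates 1 and 2 and at 67 and 53.4 CPM in NC replicates 3 and 4, so its level differed between control libraries by more than between these groups.

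Of 69768 transcripts tested, 5020 were higher and 4933 lower in siSTAT3_Vec than in NC_Vec, of which 1890 and 2273 changed at least 2-fold. At a mean of at least 10 CPM, 3161 of 15743 transcripts were higher and 2893 lower. Among 437 transcripts with unshared reads, 118 were higher and 135 lower. All 4 named transcripts kept their direction and stayed past the threshold in each of 17 alternatives, with adjusted p of at most 0.00354.

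The STAT3 siRNA effect was then set side by side between the experiments, which share no library. Of the transcripts tested in both, 2124 were lowered by siSTAT3 in the siRNA experiment, and in siSTAT3_Vec 783 of these were lower and 177 higher than in NC_Vec. Their median log2 fold change there was -0.34 (camera, preset correlation 0.01, adjusted p = 1.31e-17 over 12 list tests; adjusted p = 0.000268 with an estimated correlation). Of the 975 transcripts raised by siSTAT3, 293 were higher and 100 lower in siSTAT3_Vec, with a median log2 fold change of 0.21 (adjusted p = 1.95e-05). That call was lost with an estimated correlation (adjusted p = 0.0705 with an estimated correlation). Of the 1786 transcripts lowered by siHMGN5, 494 were lower and 265 higher in siSTAT3_Vec (median -0.10, adjusted p = 1.38e-05; adjusted p = 0.0705 with an estimated correlation), and of the 676 raised by siHMGN5, 149 were higher and 87 lower (median 0.07, adjusted p = 0.124). In all, 1353 transcripts passed the test in both experiments and 1076 of them (79.5%) moved the same way, where independent lists would give 235 in each direction. Across all 63969 transcripts the correlation of fold changes was nevertheless low, at r = 0.0515 and rho = 0.132, and 0.12 among 13316 transcripts with a mean of at least 10 CPM. In a fit of all 17 libraries, the effect itself differed between experiments for 4784 of 86839 transcripts, being more positive in the siRNA experiment for 1935 and more negative for 2849. ENST00000319234.4 fell less in the siRNA experiment (difference of log2 fold changes 1.86 ± 0.34, adjusted p = 0.00495), and ENST00000369512.2, raised there, had a log2 fold change of -0.33 ± 0.28 in siSTAT3_Vec against NC_Vec (adjusted p = 0.555), a difference of 3.62 ± 0.55 (adjusted p = 0.00143). The fit of all 17 libraries pools the spread of both experiments, so it can understate the error in the siRNA experiment. For ENST00000319234.4 the SE was 0.34 for the difference and 0.39 for siSTAT3 vs NC alone. Without siSTAT3 replicate 1, 3061 transcripts differed. The infection status of the cells and the experiment change together, so they cannot be told apart.

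The effect of ectopic HMGN5 in STAT3-depleted cells was addressed by siSTAT3_HMGN5 against siSTAT3_Vec. ENST00000258829.5 was 2.33-fold lower, from 6.33 ± 0.304 CPM in siSTAT3_Vec (SD, n = 3) to 2.72 ± 0.191 CPM in siSTAT3_HMGN5 (SD, n = 3), with a log2 fold change of -1.22 ± 0.14 (SE, adjusted p = 0.00436). ENST00000333437.4 was 2.31-fold lower, from 3.13 ± 0.368 CPM to 1.35 ± 0.169 CPM (log2 fold change -1.21 ± 0.18, adjusted p = 0.0135). ENST00000521481.5 was 2.22-fold higher, from 4.01 ± 0.147 CPM to 8.92 ± 1.37 CPM (log2 fold change 1.15 ± 0.18, adjusted p = 0.014). ENST00000368801.2 was 1.92-fold higher, from 10.2 ± 2.3 CPM to 19.7 ± 1.86 CPM (log2 fold change 0.94 ± 0.18, adjusted p = 0.0334). Each of the 4 had moved the same way in siSTAT3_Vec against NC_Vec, by -0.54, -0.95, 0.84 and 2.03 on the log2 scale in that order (adjusted p 0.000401 to 0.0339). Of the transcripts named in other comparisons, ENST00000319234.4 and ENST00000295927.3, both lower in siSTAT3_Vec than in NC_Vec, were lower again by 2-fold and 1.97-fold with HMGN5 (adjusted p = 0.00102 and 0.000798). ENST00000268042.6 moved the opposite way: it rose 2.06-fold in siSTAT3_Vec over NC_Vec (adjusted p = 4.09e-05) and was 1.53-fold lower in siSTAT3_HMGN5 than in siSTAT3_Vec (log2 fold change -0.61 ± 0.06, adjusted p = 0.00234). The remaining transcripts named in other comparisons did not pass this test in either direction (adjusted p of at least 0.0713).

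With ectopic HMGN5, 1062 of 69768 transcripts were higher and 1569 lower, of which 140 and 492 changed at least 2-fold. Among the 437 transcripts with unshared reads, 58 were higher and 109 lower. Leaving out siSTAT3_Vec replicate 1, 2 or 3 left 1381, 1190 or 1400 calls, and leaving out siSTAT3_HMGN5 replicate 1, 2 or 3 left 1668, 1506 or 1338. The calls of ENST00000333437.4, ENST00000521481.5 and ENST00000368801.2 ended in 6, 5 and 8 of 17 alternatives at the same direction, with adjusted p of at most 0.124.

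The transcripts changed by STAT3 siRNA in the vector cells were followed in the cells with HMGN5. Of the 5020 raised in siSTAT3_Vec, 481 rose further in siSTAT3_HMGN5, 304 (6.06%) were lower than in siSTAT3_Vec and 4235 did not pass that test. Of the 4933 lowered, 633 fell further, 170 (3.45%) were higher and 4130 did not pass. Compared with NC_Vec, 4226 of the raised and 4312 of the lowered transcripts were still called the same way in siSTAT3_HMGN5. The median log2 fold change against NC_Vec was 0.82 in siSTAT3_Vec and 0.89 in siSTAT3_HMGN5 for the raised set, and -0.94 and -1.09 for the lowered set. The sets were chosen on the same NC_Vec libraries, which favours such agreement, so these values do not measure how much of the change was kept. The STAT3 siRNA and HMGN5 comparisons use the siSTAT3_Vec libraries with opposite signs, which makes chance move transcripts back. The covariance of the fold changes was -0.734, against a simulated mean of -0.992 (-1.03 to -0.957), and r was -0.276 against -0.5. On the same transcripts, the covariance was -1.71, -1.7 and -1.74 without siSTAT3_Vec replicate 1, 2 and 3, below its own simulations (means -1.52, -1.52 and -1.54). In the planned refits without these libraries, which chose the transcripts anew, r was between -0.476 and -0.467. At 10 CPM or more, on the same transcripts, the covariance was -0.188, -0.147 and -0.264 in the same order. For replicates 1 and 2 it lay above the highest simulation (-0.227 and -0.221), and for replicate 3 within the simulated range (-0.294 to -0.232). With all libraries it was -0.0313 at 10 CPM or more. The simulated mean beside it was -0.216, but each simulation chose its own transcripts at that level. With different siSTAT3_Vec libraries in the 2 comparisons, the covariance was -0.026 to 0.118 over 6 splits, each above its 5 simulations (highest -0.0859). The splits reuse the same libraries. Without 1 siSTAT3_Vec library the covariance lay below its simulations by gaps of similar size, so over all transcripts the splits decide nothing. Against NC_Vec, siSTAT3_HMGN5 had 7592 transcripts higher and 7987 lower.

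Lists from the siRNA experiment, which shares no library with this comparison, gave directions free of that overlap. Of 2124 transcripts lowered by siSTAT3 there, 231 were lower and 78 higher in siSTAT3_HMGN5 than in siSTAT3_Vec, with a median log2 fold change of -0.09 (camera adjusted p = 0.00101 over 12 tests; adjusted p = 0.0235 with an estimated correlation). Of 975 raised by siSTAT3, 129 were higher and 26 lower, with a median of 0.15 (adjusted p = 5.28e-09; adjusted p = 0.0305 with an estimated correlation). Neither call held with lists made against NC replicates 3 and 4 alone, whose medians were -0.04 and 0.02, while both held with NC replicates 1 and 2 alone, with medians of -0.13 and 0.15 (camera, unadjusted, at a threshold of 0.05). Of 1786 transcripts lowered by siHMGN5, 98 were higher and 153 lower with ectopic HMGN5 (median -0.03, adjusted p = 0.295), and of 676 raised by siHMGN5, 47 were higher and 59 lower (median -0.01, adjusted p = 0.574). No direction opposite to HMGN5 depletion was thus detected with all NC libraries. With NC replicates 1 and 2 alone, the siHMGN5-lowered list was lower by the same unadjusted test (median -0.06), and with NC replicates 3 and 4 alone, the siHMGN5-raised list was lower (median -0.10).

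**Figure D4:**
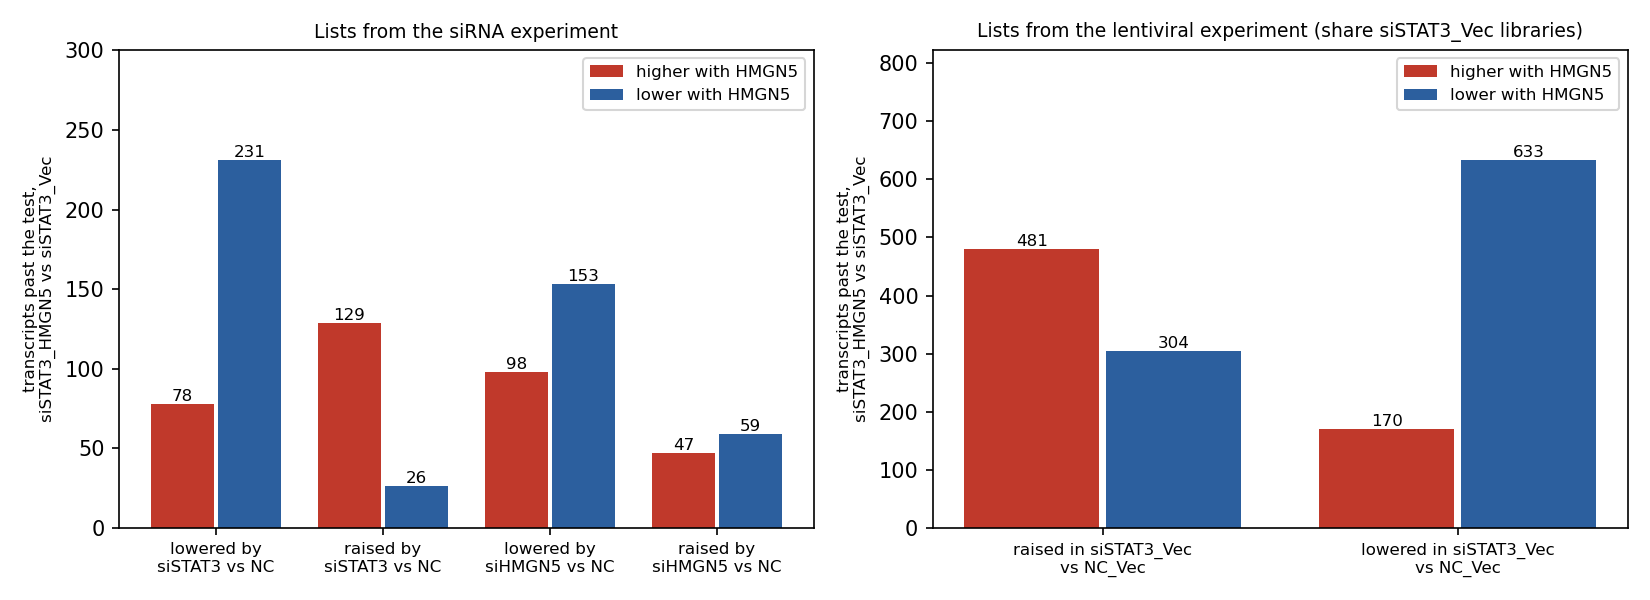
Number of transcripts past the test as higher (red) or lower (blue) in siSTAT3_HMGN5 than in siSTAT3_Vec, for lists made from the siRNA experiment with all NC libraries (left) and from siSTAT3_Vec against NC_Vec (right, sharing the siSTAT3_Vec libraries). Of the siSTAT3-lowered list 231 are lower and 78 higher, and of the siSTAT3-raised list 129 are higher and 26 lower.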

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

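No test in this part was chosen only after its result was seen, except the use of 1 NC pair for the correlation between experiments. In NC replicate 2, the 10 most abundant transcripts of the library took 7.03% of the reads, against 5.94% to 6.04% in the other NC libraries. It stood apart by Dixon's criterion for 4 samples, 1 of 13 sets of NC values tested, and chance gives about 1 in 20.

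The STAT3 siRNA effect differed between the siRNA and the lentiviral experiment for 4784 transcripts by the interaction test (edgeR quasi-likelihood, adjusted p under 0.05). Of 7 named transcripts, 6 were among them, which their selection for a large fold change in 1 of the experiments favours. The log2 fold change in the siRNA experiment minus that in the lentiviral experiment was 1.86 for ENST00000319234.4, -1.63 for ENST00000375256.4, 3.62 for ENST00000369512.2, 1.87 for ENST00000268042.6, 4.94 for ENST00000480798.1 and -2.27 for ENST00000378827.4. The level of ENST00000480798.1 was 2.08 and 2.82 CPM in NC replicates 1 and 2 and 0.369 and 0.315 CPM in NC replicates 3 and 4. The size of its difference therefore depends on the NC pair. For ENST00000404377.3 the adjusted p was 0.052. The fit behind this test pools the spread of both experiments and can understate the error in the siRNA experiment, so 4784 may be too many.

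The tables argue against the choice of NC libraries and library size as the whole cause of this difference. With 1 NC pair alone the correlation of the fold changes between experiments reached at most 0.102, so the choice of NC libraries did not bring the effects together. After thinning all libraries to 1 size, 4577 of the 4784 calls remained. The modelled error of the fold changes would leave a correlation of 0.785 for identical effects at 10 CPM or more, against 0.12 observed. That error takes libraries as independent and leaves out any error between pairs of libraries. As siSTAT3 is 1 pair, 0.785 may be too high, and error of the fold changes stays open. The vector infection, the time of the experiment and any batch change together and cannot be told apart, and a biological difference between infected and uninfected cells was not tested.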

How the results depend on the processing

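The fits limited to unshared reads, and the use of 1 NC pair for the interaction, the correlations and the lists, were chosen after the data were seen. Of 96 counts of transcripts under alternatives, 62 stayed within 1.5 times the main count, 25 were lower and 9 higher, and of 46 counts without 1 library, 29 stayed and 17 were lower. Of 288 values of the named transcripts, 238 kept their direction and call, 50 lost the call and 0 reversed. Gene lists, the levels of STAT3 and HMGN5 and sums per gene were not run, since the files do not pair transcripts with genes. A lone library left in a group is assumed to vary like the other groups. At the depth and spread of these libraries, 25% of simulated 4-fold changes were recovered for siSTAT3 vs NC and 84% for siSTAT3_Vec vs NC_Vec, and neither depth nor the number of libraries was varied.

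In the order siSTAT3 vs NC, siHMGN5 vs NC, siSTAT3 vs siHMGN5, siSTAT3_Vec vs NC_Vec, siSTAT3_HMGN5 vs siSTAT3_Vec, siSTAT3_HMGN5 vs NC_Vec and the interaction, an adjusted p under 0.01 left 845, 575, 674, 5366, 858, 9200 and 2348 transcripts. Limiting the test to unshared reads left 167, 108, 151, 253, 167, 283 and 158, with fewer transcripts tested by construction. The DESeq2 Wald test called 10602, 9891, 10178, 16965 and 8078 in the first 5 and 10995 for the interaction, and the cause was not tested. An absolute log2 fold change of at least 1 left 2083 for siSTAT3 vs NC, 1580 for siHMGN5 vs NC, 4163 for siSTAT3_Vec vs NC_Vec, 632 for siSTAT3_HMGN5 vs siSTAT3_Vec and 8116 for siSTAT3_HMGN5 vs NC_Vec. Without a low-count filter, 1638 were called for siHMGN5 vs NC and 1627 for siSTAT3_HMGN5 vs siSTAT3_Vec, and with only the compared groups in the fit 1448 for siHMGN5 vs NC. The cause was not tested. With NC replicates 3 and 4 only and the other pair left out of the fit, unlike the fit with the pairs as separate groups that gave 7321 and 7656, 6259 were called for siSTAT3 vs NC, 6249 for siHMGN5 vs NC and 9318 for the interaction, where the spread between NC pairs is absent by construction.

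The titles link libraries of different groups only by number. Deviations of same-numbered libraries from their group means correlated at 0.00219 to 0.0516 in the siRNA experiment and -0.107 to 0.0498 in the lentiviral one. In the siRNA experiment this check cannot decide on pairing: NC deviations carry the difference between the NC pairs, and those of 2 libraries mirror each other. With the replicate block, 1622 transcripts were called for siSTAT3 vs NC, 902 for siHMGN5 vs NC and 1156 for siSTAT3_HMGN5 vs siSTAT3_Vec, and the other counts stayed within 1.5 times.

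Leaving out 1 library gave 775 to 2349 calls for siSTAT3 vs NC, 551 to 1838 for siHMGN5 vs NC, 844 to 972 for siSTAT3 vs siHMGN5, 1190 to 1668 for siSTAT3_HMGN5 vs siSTAT3_Vec and 3061 to 5393 for the interaction. The correlation of siSTAT3 and siHMGN5 fold changes was 0.324 to 0.383 without 1 library, 0.478 with NC replicates 1 and 2 only and 0.53 with NC replicates 3 and 4 only. That of siSTAT3 in both experiments was 0.132 as Spearman rho, 0.12 at 10 CPM or more, 0.145 among transcripts past the threshold in either and 0.203 with unshared reads. That of siSTAT3_Vec vs NC_Vec and siSTAT3_HMGN5 vs siSTAT3_Vec was -0.476 to -0.269 without 1 library (lowest without a siSTAT3_Vec library, jackknife SE 0.258) and reversed to 0.133 with unshared reads. Its covariance was -2.22 to -1.1 without 1 library when transcripts were chosen anew each time, which changes the chance value too. The cause was not tested for these correlations.

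Of 28 list directions under ectopic HMGN5, 22 stayed on their side of the threshold, 2 lost a call and 4 gained one. Without 1 siSTAT3_Vec or siSTAT3_HMGN5 library, the siSTAT3 lists kept their call in each case and the siHMGN5 lists, which had none, gained none, and the lists were not remade without single libraries of the siRNA experiment. With NC replicates 3 and 4 only, the siSTAT3 lists lost the call (medians -0.0376 lowered, 0.0154 raised) and the siHMGN5-raised list gained one (-0.103). The siHMGN5-lowered list gained one with NC replicates 1 and 2 only (-0.0639), at adjusted p under 0.01 (-0.0509) and at an absolute log2 fold change of at least 1 (-0.0664). The cause was not tested.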

Other observations

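The tests chosen only after the result was seen are the abundant transcripts described first, the correlation of single libraries with the NC pairs, the comparison of the covariance over all libraries with simulations, the share that moved the same way in the leave-outs, the use of the planned list tests without single libraries as the test of a single library, and the lists from 1 NC pair.

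The 10 transcripts with the highest mean in NC took 6.21% ± 0.51 of the reads in NC (SD, n = 4), 9.87% ± 0.981 in siHMGN5 (n = 2) and 12.2% ± 0.203 in siSTAT3 (n = 2), and the share of reads on transcripts under 300 bases was higher in the same libraries (1.56% to 1.7% against 1.15% to 1.26% in NC). In siSTAT3, 8 of the 10 were higher and 1 lower than in NC (edgeR quasi-likelihood test, adjusted p under 0.05; median log2 fold change 0.94), and against each NC pair 8 were higher and 2 lower. In siHMGN5, 5 were higher and 1 lower than in NC (median 0.56), with 4 higher and 2 lower against NC replicates 1 and 2, and 5 higher and 2 lower against NC replicates 3 and 4. In the lentiviral experiment the same 10 took 4.53% ± 0.178 in NC_Vec, 4.39% ± 0.0166 in siSTAT3_Vec and 4.46% ± 0.235 in siSTAT3_HMGN5 (n = 3 each), and 2 were higher and 1 lower in siSTAT3_Vec than in NC_Vec (median -0.06).

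NC replicates 1 and 2 stood apart from NC replicates 3 and 4 by 3262 transcripts. A trend with transcript length and the most abundant transcripts were argued against as the whole cause: 3164 calls remained after removing the length trend, and 3214 of 3235 without the 100 most abundant transcripts. Thinning to 1 library size left 3184 calls but removed too few reads to test library size. All 4 siRNA libraries correlated better with NC replicates 1 and 2 (r 0.758 to 0.769) than with NC replicates 3 and 4 (0.744 to 0.751). Shared handling of those 6 libraries would give this order, as would any other cause that set NC replicates 3 and 4 apart. The 4 siRNA libraries are 2 close pairs, so they are not 4 independent cases. The labels give no date or batch for the NC libraries, and no biological explanation was tested.

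Of the 1588 transcripts called both for STAT3 siRNA in vector cells and for ectopic HMGN5, 1114 moved the same way in both. Error of the shared siSTAT3_Vec libraries moves transcripts in opposite ways, so it could not make such an excess, and the share that moved the same way is no test of it. That share was at least 60% in each of 9 leave-outs. The covariance of -0.734 lay above the highest simulation (-0.957). With separate siSTAT3_Vec libraries the covariance lay above its simulations in 6 of 6 splits and was above 0 in all at 10 CPM or more (0.00635 to 0.093). Over all transcripts it ran from -0.026 to 0.118, and the 6 splits reuse the same libraries. On the same transcripts, the covariance was above its simulations in 6 of 9 leave-outs, and below them without siSTAT3_Vec replicate 1, 2 or 3. Over all transcripts the excess was thus absent in each of these leave-outs, so a single library is not excluded, and the cause was not tested. The simulations missed the covariance there by gaps of similar size to those in the 6 splits. Over all transcripts the splits therefore decide nothing either. At 10 CPM or more the covariance was above its simulations in 8 of 9 leave-outs, and siSTAT3_Vec replicate 3 as a single library stays open there. Removing a length trend moved nothing (covariance -0.733). For the siSTAT3 lists of the siRNA experiment, the tables argue against a single lentiviral library (highest camera p over 6 leave-outs 0.00307), and the choice of NC libraries stays open, since lists called against both pairs kept the direction (larger p 0.000196) but lists from NC replicates 3 and 4 alone did not pass (larger p 0.831), so that ectopic HMGN5 may add to the change after STAT3 depletion is an open hypothesis, found and tested on the same data.

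The groups of the lentiviral experiment were also compared under other splits of the 6 libraries of each comparison. In each, 1 of 10 splits, the real one, gave as many calls: 9279 for siSTAT3_Vec vs NC_Vec, 2409 for siSTAT3_HMGN5 vs siSTAT3_Vec and 14432 for siSTAT3_HMGN5 vs NC_Vec. The highest other split gave 0 in each by edgeR, the 1 tool run on them, with 1265, 1619 and 891 transcripts at an unadjusted p under 0.05 against 17531, 10700 and 21852 in the real splits. Every other split mixed libraries of the compared treatments in each group, so a treatment effect would widen the spread within groups. That lowers the calls of the other splits by construction, and their counts are no chance baseline for the real one. With 10 splits no share under 0.05 can be reached either, so this comparison cannot decide whether the calls arose by chance.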
